A study of Mus musculus with 17 samples.

How the data were processed

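Lung RNA was profiled in 17 Balb/c mice on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per mouse. Per the labels, total RNA was extracted with RNeasy columns and labelled with biotin. The saline group (6 mice) received saline at sensitization and challenge. The isotype group (5 mice) received ovalbumin at both steps and an isotype antibody. The anti-RGMb group (6 mice) received ovalbumin at both steps and a monoclonal antibody against RGMb, a co-receptor for bone morphogenetic proteins (BMPs) that binds neogenin. The labels give no antibody for saline mice and no group with anti-RGMb but without ovalbumin, so changes called the allergen's include any of the isotype antibody, and an action of anti-RGMb on unchallenged lung cannot be told apart from one on the response to ovalbumin. All lungs were collected at 1 time point of the treatment. The mice came from 2 experiments, with 3 mice of each group in experiment 1 and with 3 saline, 3 anti-RGMb and 2 isotype mice in experiment 2. Mice of experiment 1 are named by number (1, 2 and 3) and mice of experiment 2 as 1-2, 2-2 and 3-2. Residuals of same-numbered mice of 1 group correlated at -0.18 to 0.29, above 0.1 in 2 of 8 pairs, so a link stays open, and mice were treated as unpaired.

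The deposited values are linear probe set intensity, made by the authors with RMA (background correction, normalization and summary of array probes) per the submitters' processing notes. The RMA version is not given in the sources used here. The scale was read from the values, which were never negative and had array medians of 120 to 125 in experiment 1 and of 362 to 386 in experiment 2. The log2 of each value was taken here, with no added constant. Because the level differed between experiments, the experiment was a fixed term of every fit.

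Of 24679 probe sets, 21354 had 1 gene symbol, 1275 had several and 2050 had none. Probe sets with 1 symbol were used, and for the 893 genes with more than 1 probe set the brightest over all arrays was kept, which left 19751 genes. The number of arrays limits the precision of every value.

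A linear model with a mean per group and a term for the experiment was fitted to each gene with limma 3.58.1 in R 4.3.3, with moderated variances (eBayes, prior degrees of freedom 4.32). The 3 comparisons were isotype minus saline, anti-RGMb minus isotype, and anti-RGMb minus saline. Benjamini-Hochberg adjusted p under 0.05 over all 19751 genes of a comparison was the threshold, and all tests were 2-sided. Values after ± are standard errors of the log2 difference unless SD is written. A second model with a mean per group and experiment gave the differences within each experiment and the interaction, that is, the difference between the experiments' differences. In simulated data the fit recovered 88.1% to 94.0% of changes of 0.5 log2 units and 97.0% to 100% of those of 1 unit. Of its calls, 14 of 204, 13 of 205 and 20 of 216 were false.

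Gene lists were written for 34 cell types and pathways. They cover type 2, goblet cell and mucus genes, immune cell types, resident lung cell types, the hub of RGM proteins, neogenin and BMPs with its target genes, pathways such as proliferation and interferon, and tissues that lung samples can carry (heart, fat, thymus, blood). Some genes stand in several lists: 13 of the 31 measured type 2 genes, 16 of the 24 T helper 2 genes and 10 of the 31 dendritic cell genes are also in another list. Each list was compared with all other genes by camera (limma), the source of every adjusted p given for a list, with a preset correlation between genes of 0.01, over 102 list comparisons, adjusted within each comparison. A list's median is that of its members' log2 changes, and its counts are of members past the limma threshold, given a second time with p adjusted within the list. The alternatives were camera with a correlation estimated for each list (0.03 to 0.89) and an exact permutation of the list mean within experiments. Il1rl1 and Fcgbp, planned as list members, had no probe set with 1 symbol and are not analysed here.

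The allergen score of a mouse is the mean log2 level of the 200 genes most raised by the allergen minus that of the 200 genes most lowered, where the genes were chosen in the other experiment and the saline mean of the mouse's own experiment was subtracted. It was tested by exact permutation of group labels within experiments. Relations between changes were computed across genes, as Pearson's r and Spearman's rho, for 5 pairs of comparisons, and genes are not independent replicates. The value that shared arrays alone give was simulated with 100 sets of arrays that carried no effect.

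Named genes followed a rule. For each comparison they are, among genes past the threshold with the same sign in both experiments, the 12 largest rises and the 12 largest falls, and up to 4 members of each described list with the smallest p. The genes of the hub and its targets (Rgmb, Neo1, Rgma, Bmp2, Bmp4, Bmpr1a, Bmpr2, Id1, Id2, Id3, Smad6, Smad7) and of type 2 inflammation (Pdcd1lg2, Il4, Il5, Il13, Il33, Il25, Il17rb, Muc5ac, Clca1, Ccl11, Ccl24, Chil3, Chil4, Retnla, Arg1, Foxp3, Il10, Il17a, Ifng) were always included. Any gene outside this rule is said to have been chosen after its values were seen. The groups, comparisons, lists, thresholds, naming rule and most alternatives were fixed before the data were examined.

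The alternatives were no term for the experiment, mouse number as a fixed or random block, only the 2 groups compared, 1 experiment alone, a variance trend with robust estimation, array weights, and the dimmest 40% of genes left out. Further ones were the mean of a gene's probe sets, every probe set, quantile normalization, median centring, a 1.5-fold minimum, an adjusted p under 0.10, and each mouse left out in turn. For the score they were 100 or 50 genes per direction and genes of 1 direction. After seeing the data, 3 more were added: without the 3 arrays of experiment 2 with the highest lower quartile, the lower quartile as a covariate, and experiment 2 rescaled by 1 slope.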

Results

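The data are lung mRNA levels of 17 Balb/c mice for 19751 genes. The saline and anti-RGMb groups held 6 mice each and the isotype group 5. The title of the series concerns blockade of the hub formed by neogenin, RGMb and BMPs in allergic airways. Arrays within an experiment were alike, with a lowest correlation between arrays across genes of 0.975 in experiment 1 and 0.970 in experiment 2. The first principal component held 58.1% of the variance after subtraction of the experiment means, and ordered the arrays from saline over anti-RGMb to isotype mice. The second held 11.3%.

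Isotype and saline mice were compared to ask what the allergen did to the lung under a control antibody. Genes of type 2 inflammation were among the largest rises (5 isotype and 6 saline mice). Rnase2a, a ribonuclease of the eosinophil-associated family, was higher by 8.10 ± 0.41 log2 units (adjusted p = 1.2e-10). The chemokine gene Ccl8 was higher by 6.43 ± 0.19, the goblet cell gene Clca1 by 5.37 ± 0.64, and the arginine-degrading enzyme gene Arg1 by 4.99 ± 0.52. The largest fall was that of Pon1, which encodes paraoxonase of club cells and liver (-3.13 ± 0.23). In all, 7034 genes passed the threshold, 2878 higher and 4156 lower, and 531 of the higher and 79 of the lower ones changed at least 2-fold. Of the 7034, 7031 had the same sign in both experiments. In the model of both experiments, experiment 1 gave 1740 higher and 2285 lower genes and experiment 2 gave 2709 and 3129.

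Other large rises were Saa3 (4.97), an acute phase protein, Slc26a4 (4.83) and Chil4 (3.87 and 4.84 in experiments 1 and 2). So were Retnla (4.73) and Chil3 (3.96), markers of alternatively activated macrophages, and Mmp12 (4.21), macrophage elastase. Pdcd1lg2, which encodes PD-L2, a ligand of PD-1 and of RGMb, rose by 3.71 ± 0.15 (adjusted p = 9.3e-12). Of 261 genes that the naming rule covers, 22 lay below the arrays' lower quartile in saline mice of both experiments, so the sizes of their rises are uncertain. They include Rnase2a, Ccl8, Clca1, Chil4, Cd5l, Pdcd1lg2, Il5, Il10, Mcpt1, Mcpt2, AA467197, Chl1, Serpinb2, Prg4, Mcpt8, Il21, Il13ra2 and Epx. After Pon1, the largest falls were in Myl7 (-2.26), Myl4 (-2.15), Myoz2 (-1.83), Tnnt2 (-1.82) and Tnni3 (-1.80), all of striated muscle, and in Igfbp3 (-1.90 ± 0.11), Sult1d1 (-1.70), Fabp1 (-1.69) and the endothelial gene Esm1 (-1.66). The heart muscle genes Myh6 (-1.67) and Pln (-1.57) also fell, but without isotype mouse 1 neither passed (Myh6 -1.40, adjusted p = 0.0528, and Pln -1.34, adjusted p = 0.0612), and Pln did not pass without saline mouse 1 (-1.31, adjusted p = 0.0591) or isotype mouse 3 (-1.34, adjusted p = 0.058).

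The list of type 2 cytokines, chemokines and effector genes rose (median 1.19, adjusted p = 1.3e-17). Of 31 genes, 24 were higher, 1 lower and 6 not past (24 and 1 within the list). Il13 (0.99 ± 0.13), Il4 (1.07 ± 0.17) and Il5 (0.42 ± 0.11), the cytokines of type 2 cells, and Il33 (1.19 ± 0.10), an epithelial alarmin, were higher, as were the eosinophil-attracting chemokines Ccl11 (3.33 ± 0.14) and Ccl24 (2.72 ± 0.22). Il17rb, the receptor chain for IL-25, rose (0.50), while Il25 passed in none of the 3 comparisons (0.05, 0.02 and 0.07). Eosinophil markers rose (median 1.53, adjusted p = 3.9e-13). Of 16 genes, 13 were higher, 0 lower and 3 not past (13 and 0 within the list). They included Adgre1 (2.15) and Alox15 (3.53). Goblet cell and mucus genes rose (median 0.36, adjusted p = 2.1e-06, 0.145 with estimated correlation). Of 34 genes, 19 were higher, 2 lower and 13 not past (19 and 2 within the list). The mucin gene Muc5ac (2.27 ± 0.63) and Pigr (1.79), which carries IgA into the airway, were higher. Mast cell and basophil markers rose (median 0.48, adjusted p = 9.2e-05, 0.0917 with estimated correlation). Of 20 genes, 14 were higher, 3 lower and 3 not past (14 and 3 within the list). Within this list Cpa3 (1.57) and Mcpt8 (1.96) were higher and Gata2 (-0.68) and Kit (-0.45) lower, and with the dimmest 40% of genes left out the list was not called (median 0.04, adjusted p = 0.839).

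Markers of T helper 2 and innate lymphoid group 2 cells rose (median 0.72, adjusted p = 4.7e-10). Of 24 genes, 20 were higher, 1 lower and 3 not past (20 and 1 within the list). Il2ra (1.91), Pdcd1 (1.55) and Maf (0.76) were higher. Regulatory T cell markers were higher (median 0.69, adjusted p = 7.3e-09, 0.0571 with estimated correlation). Of 20 genes, 16 were higher, 2 lower and 2 not past (16 and 2 within the list). They included Foxp3 (0.76 ± 0.08), the lineage's transcription factor, and Il10 was higher by 0.62 ± 0.16. T cell markers rose (median 0.38, adjusted p = 1.8e-07, 0.219 with estimated correlation). Of 28 genes, 18 were higher, 2 lower and 8 not past (18 and 2 within the list). They included Icos (1.39) and Ctla4 (1.18). Type 1 and type 17 T cell genes rose (median 0.24, adjusted p = 2.5e-05, 0.146 with estimated correlation). Of 21 genes, 9 were higher, 0 lower and 12 not past (11 and 0 within the list). Ciita (1.26) and Cxcl9 (2.48) were higher. Ifng was at 0.21 (adjusted p = 0.0607, and past the threshold without isotype mouse 1, 0.26, adjusted p = 0.0161, or without anti-RGMb mouse 3-2, 0.20, adjusted p = 0.0486). Il17a passed in none of the 3 comparisons (0.09, -0.06 and 0.03).

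B cell markers were higher (median 0.40, adjusted p = 4.0e-08, 0.154 with estimated correlation). Of 29 genes, 21 were higher, 2 lower and 6 not past (22 and 3 within the list). They included the B cell chemokine Cxcl13 (3.12). Plasma cell and immunoglobulin genes rose (median 0.53, adjusted p = 4.1e-07, 0.143 with estimated correlation). Of 19 genes, 16 were higher, 2 lower and 1 not past (16 and 2 within the list). They included Irf4 (2.15), needed for plasma cell differentiation, and Jchain (3.39), which joins IgA and IgM. Natural killer cell markers were not called (median -0.01, adjusted p = 0.234, 5 higher, 2 lower and 12 not past, 5 and 2 within the list), and their mean was 0.12.

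Among myeloid cells, interstitial macrophage and monocyte markers rose (median 1.44, adjusted p = 3.9e-14). Of 27 genes, 19 were higher, 3 lower and 5 not past (19 and 3 within the list). The complement genes C1qa (2.43) and C1qb (2.25), Folr2 (2.40) and Ms4a4a (3.06) were higher. Dendritic cell markers rose (median 0.58, adjusted p = 1.5e-13). Of 31 genes, 22 were higher, 2 lower and 7 not past (23 and 2 within the list). They included Itgax (2.13) and Pdcd1lg2. Alveolar macrophage markers went both ways and were higher as a list (median 0.47, adjusted p = 6.7e-06, 0.139 with estimated correlation). Of 24 genes, 13 were higher, 5 lower and 6 not past (14 and 5 within the list). Neutrophil markers were higher (median 0.43, adjusted p = 5.6e-05, 0.14 with estimated correlation). Of 26 genes, 13 were higher, 0 lower and 13 not past (14 and 1 within the list).

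Proliferation genes rose (median 1.84, adjusted p = 2.2e-36, 0.0354 with estimated correlation). Of 35 genes, 35 were higher, 0 lower and 0 not past (35 and 0 within the list). They included Kif11 (2.32), a mitotic motor. Complement and pattern recognition genes rose (median 0.41, adjusted p = 8.2e-12). Of 36 genes, 22 were higher, 2 lower and 12 not past (23 and 2 within the list). Eicosanoid pathway genes were higher (median 0.26, adjusted p = 2.1e-05). Of 33 genes, 18 were higher, 5 lower and 10 not past (18 and 5 within the list). Endoplasmic reticulum folding and secretion genes rose (median 0.21, adjusted p = 7.7e-09, 0.139 with estimated correlation). Of 34 genes, 21 were higher, 0 lower and 13 not past (21 and 1 within the list). Type I interferon stimulated genes were higher (median 0.34, adjusted p = 0.00047, 0.543 with estimated correlation). Of 30 genes, 12 were higher, 0 lower and 18 not past (12 and 0 within the list). Fibroblast and extracellular matrix genes went both ways (median 0.32, adjusted p = 0.00067, 0.238 with estimated correlation). Of 34 genes, 17 were higher, 10 lower and 7 not past (17 and 11 within the list). Timp1 (3.18) and Inhba (2.15) were higher.

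Lists of resident lung cells fell. Endothelial markers were lower (median -0.47, adjusted p = 7.7e-09, 0.139 with estimated correlation). Of 31 genes, 3 were higher, 24 lower and 4 not past (3 and 24 within the list). Those lower included Aplnr (-0.84) and Tek (-0.88). Ciliated cell markers were lower (median -0.43, adjusted p = 4.3e-09, 0.145 with estimated correlation). Of 32 genes, 0 were higher, 27 lower and 5 not past (0 and 27 within the list). Club cell markers fell (median -0.47, adjusted p = 1.0e-06, 0.132 with estimated correlation). Of 27 genes, 1 was higher, 17 lower and 9 not past (1 and 18 within the list). The secretoglobin gene Scgb3a2 (-1.52 ± 0.10) and Cyp2f2 (-0.71) were lower, while Retnla was higher, and the exact permutation of the list mean did not pass (adjusted p = 0.0762). Alveolar epithelial markers were lower (median -0.29, adjusted p = 0.00047, 0.304 with estimated correlation). Of 30 genes, 3 were higher, 18 lower and 9 not past (3 and 19 within the list). Smooth muscle and pericyte markers were lower (median -0.25, adjusted p = 0.0009, 0.279 with estimated correlation). Of 26 genes, 1 was higher, 15 lower and 10 not past (1 and 17 within the list). Those lower included Des (-0.48) and Cnn1 (-0.79). Heart and skeletal muscle markers fell (median -0.75, adjusted p = 3.5e-05, 0.355 with estimated correlation). Of 32 genes, 0 were higher, 23 lower and 9 not past (0 and 25 within the list). Isotype mouse 2 stood apart from the other isotype mice (list mean -0.31 against -0.95 to -0.89).

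The hub itself was lower in isotype mice. Components of the RGM, neogenin and BMP hub fell (median -0.43, adjusted p = 4.0e-08). Of 30 genes, 1 was higher, 21 lower and 8 not past (1 and 22 within the list). Rgmb fell by 0.43 log2 units (-0.43 ± 0.05, adjusted p = 5.2e-06) and its receptor gene Neo1 by 0.52 (-0.52 ± 0.06, adjusted p = 9.2e-07), and Rgma (-0.46), Bmp2 (-0.48), Bmp4 (-0.59), Bmpr1a (-0.48), Bmpr2 (-0.44) and Bmp6 (-1.03) were lower too. Pdcd1lg2, also in this list, was the 1 member that rose. BMP target genes and antagonists fell (median -0.50, adjusted p = 7.5e-07, 0.139 with estimated correlation). Of 31 genes, 1 was higher, 20 lower and 10 not past (1 and 21 within the list). Smad6 (-0.78) and Smad7 (-0.43), the inhibitory Smads, and Id1 (-0.32) and Id3 (-0.75), direct BMP targets, were lower, Id2 passed in none of the 3 comparisons (0.08, -0.10 and -0.02), and the antagonist gene Fst rose (1.03).

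Circadian clock genes were not called (median -0.04, adjusted p = 0.993, 4 higher, 5 lower and 9 not past, 4 and 5 within the list), with Bhlhe40 (1.11) higher and Cry2 (-0.72) lower. Immediate early and stress genes were not called (median -0.02, adjusted p = 0.989, 7 higher, 14 lower and 12 not past, 10 and 15 within the list), with Egr2 (1.71) and Atf3 (1.42) higher and Ccn1 (-0.96) lower. Nor were erythroid markers (median -0.20, adjusted p = 0.253, 1 higher, 6 lower and 6 not past, 2 and 8 within the list) or adipose markers (median -0.17, adjusted p = 0.332, 2 higher, 5 lower and 13 not past, 2 and 5 within the list), though the exact permutation of the last passed (adjusted p = 0.0182). Thymus and immature lymphocyte markers were not called either (median -0.01, adjusted p = 0.855, 3 higher, 4 lower and 16 not past, 3 and 4 within the list), with a mean of 0.03. With a preset correlation 28 of 34 lists were called (20 higher and 8 lower). With an estimated correlation 9 held (adjusted p = 0.020 to 0.047): type 2, eosinophil, T helper 2, interstitial macrophage, dendritic cell, proliferation, eicosanoid, complement and hub genes. Without a term for the experiment, limma called 35 genes (481 at unadjusted p under 0.05), since the level of the arrays differed between experiments.

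Anti-RGMb and isotype mice were compared to ask what the antibody changed in allergen-exposed lungs (6 and 5 mice). Many genes that the allergen had raised were lower with the antibody. Pdcd1lg2 fell by 2.35 log2 units (-2.35 ± 0.15, adjusted p = 1.7e-07), from 3.69 ± 0.47 above saline (SD, n = 5) in isotype mice to 1.36 ± 0.18 (SD, n = 6) with the antibody. The alarmin gene Il33 (-0.99 ± 0.10, adjusted p = 5.3e-06), Il13 (-0.80 ± 0.13, adjusted p = 0.00021) and the eosinophil chemokine genes Ccl11 (-1.73 ± 0.14) and Ccl24 (-1.62 ± 0.22) were lower. Clca1 (0.72 ± 0.64, adjusted p = 0.48) and Muc5ac (-0.21 ± 0.63, adjusted p = 0.855), genes of mucus-making cells, were not past the threshold. Past it were 4180 genes, 2199 higher (17 at least 2-fold) and 1981 lower (121 at least 2-fold), all with the same sign in both experiments. Experiment 1 gave 661 higher and 618 lower genes and experiment 2 gave 1705 and 2226.

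**Figure D1:**
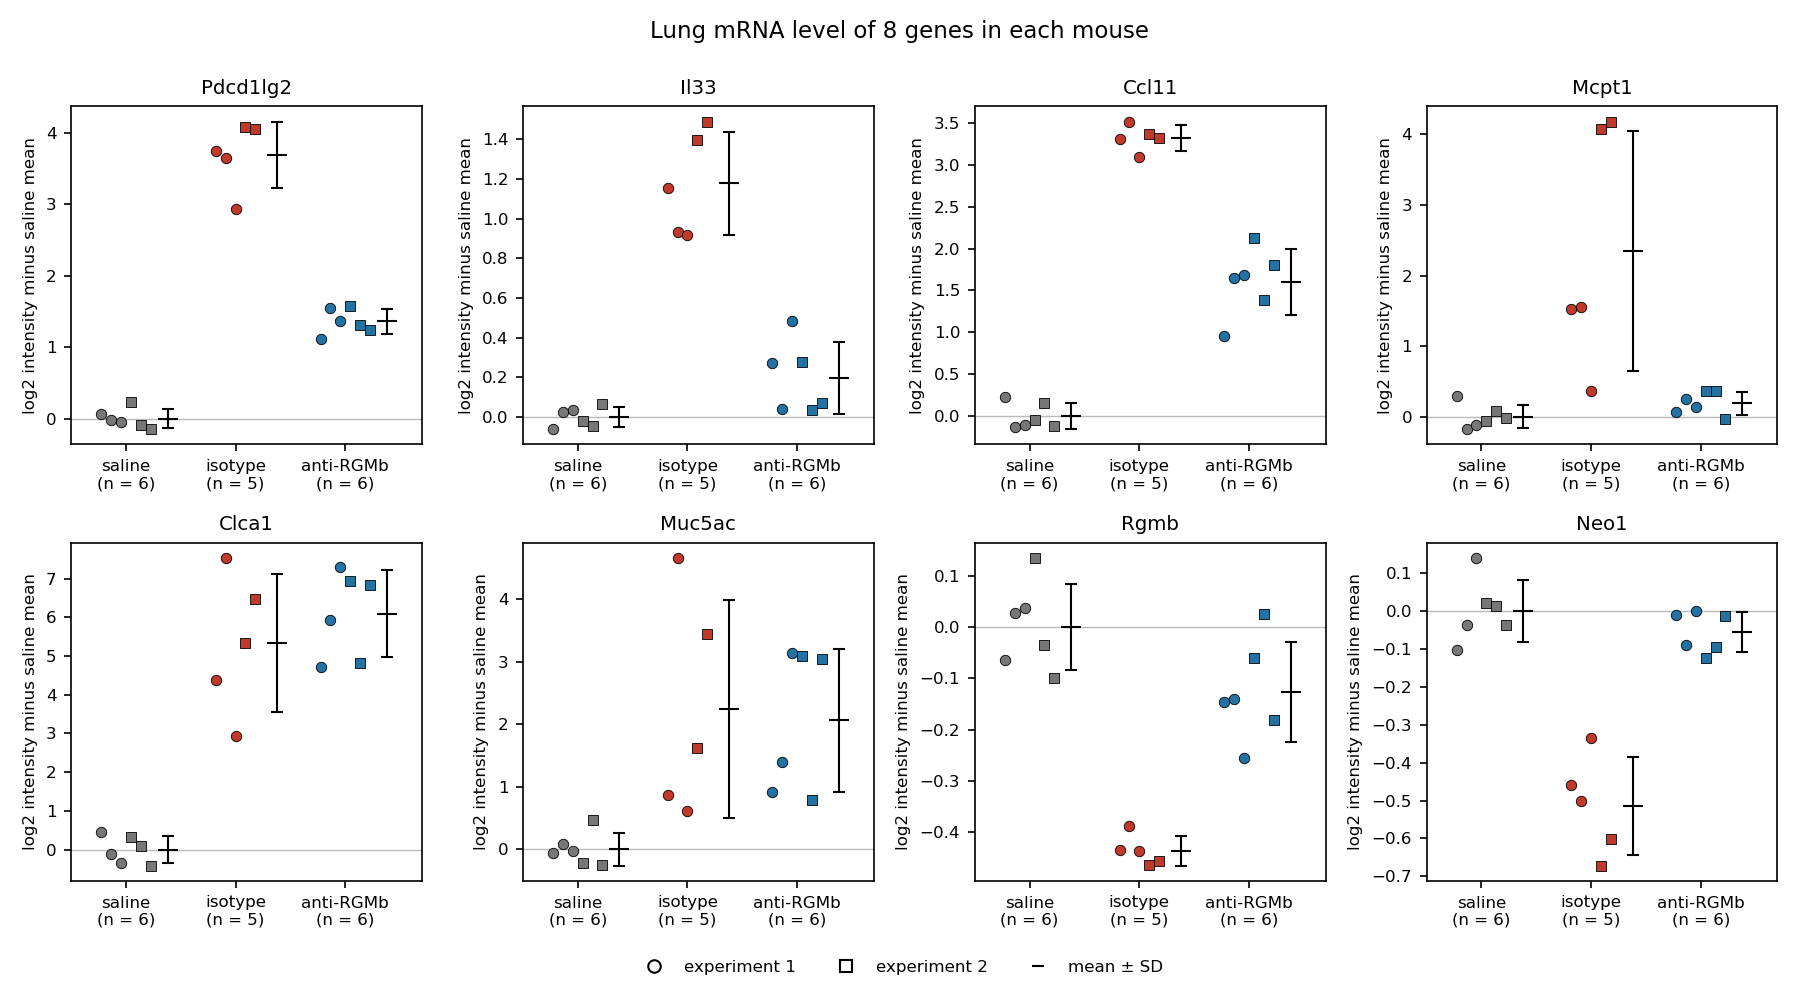
Log2 intensity of 8 genes in each mouse minus the saline mean of its experiment (vertical axis, log2 units) in saline (n = 6), isotype (n = 5) and anti-RGMb mice (n = 6), with circles for experiment 1, squares for experiment 2 and bars for the mean ± SD. Il33 was 1.18 ± 0.26 above saline in isotype and 0.20 ± 0.18 in anti-RGMb mice, while Clca1 was 5.33 ± 1.79 and 6.09 ± 1.12.

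The largest falls after Pdcd1lg2 were in the mast cell protease genes Mcpt1 (-2.24 ± 0.43) and Mcpt2 (-2.21 ± 0.49), AA467197 (-2.16), Tm4sf19 (-2.08), the haemoglobin scavenger receptor gene Cd163 (-2.02), Chl1 (-1.93), Cxcl13 (-1.90), the cystine transporter gene Slc7a11 (-1.82) and Inhba (-1.72). Arg1 fell too (-1.77 ± 0.52, adjusted p = 0.0203), but not past the threshold without isotype mouse 2-2 (-1.69, adjusted p = 0.0553), and by less without anti-RGMb mouse 1 (-1.12, adjusted p = 0.00408). The largest rises were in Pon1 (2.12 ± 0.23), the striated muscle genes Myl4 (1.68), Tnnt2 (1.53), Myh6 (1.48) and Myl7 (1.47), Igfbp3 (1.34 ± 0.11), Upk3b (1.21), Ppbp (1.15), Fabp1 (1.12), Faim2 (1.12) and Dpep1 (1.10). Myh6 lost its call in 11 fits, without saline mouse 3, 1-2 or 3-2, isotype mouse 1, 3 or 1-2, or anti-RGMb mouse 1, 2, 3, 1-2 or 3-2 (weakest without isotype mouse 1, 1.22, adjusted p = 0.132). Myl7 lost it in 9, without isotype mouse 1, 3, 1-2 or 2-2 or anti-RGMb mouse 1, 2, 3, 1-2 or 3-2 (weakest without anti-RGMb mouse 3, 1.21, adjusted p = 0.0944), and Ppbp without isotype mouse 1-2 (0.97, adjusted p = 0.0683) or anti-RGMb mouse 2 (0.97, adjusted p = 0.0527).

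Type 2 cytokines, chemokines and effector genes fell (median -0.60, adjusted p = 1.1e-10, 0.0704 with estimated correlation). Of 31 genes, 0 were higher, 17 lower and 14 not past (0 and 21 within the list). Il13ra2 (-1.07), the decoy receptor for IL-13, Ccl22 (-0.80) and Il4 (-0.60, adjusted p = 0.0139) were among those lower. Chil4 was lower (-1.37, adjusted p = 0.026), a call lost without isotype mouse 2-2 (-1.17, adjusted p = 0.0919), isotype mouse 2 (-1.17, adjusted p = 0.0745), anti-RGMb mouse 1 (-1.09, adjusted p = 0.0645) or anti-RGMb mouse 2-2 (-1.19, adjusted p = 0.0609). Il5 (-0.37, adjusted p = 0.0258) was lower with all mice, but not without isotype mouse 2-2 (-0.25, adjusted p = 0.099), isotype mouse 1 (adjusted p = 0.0587), isotype mouse 1-2 (adjusted p = 0.0547), anti-RGMb mouse 3 (adjusted p = 0.0689) or anti-RGMb mouse 1-2 (adjusted p = 0.053). Chil3 (-0.47, adjusted p = 0.108) and Retnla (-0.60, adjusted p = 0.151) were not past the threshold. Il17rb was at -0.23 (adjusted p = 0.0934, and past it without isotype mouse 3, -0.28, adjusted p = 0.0467). Anti-RGMb mouse 1 had the lowest type 2 list mean of its group (0.82, against 1.34 to 1.63).

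Eosinophil markers fell (median -0.46, adjusted p = 2.7e-06, 0.112 with estimated correlation). Of 16 genes, 0 were higher, 9 lower and 7 not past (0 and 10 within the list). They included the peroxidase gene Epx (-1.14) and Alox15 (-1.22). Markers of T helper 2 and innate lymphoid group 2 cells were lower (median -0.40, adjusted p = 2.7e-07, 0.112 with estimated correlation). Of 24 genes, 1 was higher, 14 lower and 9 not past (2 and 17 within the list). Regulatory T cell markers were lower (median -0.46, adjusted p = 9.1e-07, 0.115 with estimated correlation, 2 higher, 13 lower and 5 not past, 3 and 13 within the list). They included Foxp3 (-0.38, adjusted p = 0.0016), and Il10 fell (-0.68). T cell markers were lower (median -0.28, adjusted p = 2.6e-07, 0.269 with estimated correlation, 0 higher, 14 lower and 14 not past, 0 and 16 within the list). B cell markers fell (median -0.34, adjusted p = 8.9e-10, 0.153 with estimated correlation). Of 29 genes, 0 were higher, 16 lower and 13 not past (0 and 21 within the list). Plasma cell and immunoglobulin genes were lower (median -0.29, adjusted p = 1.2e-05, 0.223 with estimated correlation, 0 higher, 7 lower and 12 not past, 0 and 9 within the list). The exact permutation gave adjusted p = 0.0654.

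Type 1 and type 17 T cell genes were lower (median -0.14, adjusted p = 0.0013, 0.31 with estimated correlation). Of 21 genes, 0 were higher, 6 lower and 15 not past (0 and 6 within the list). They included Ciita (-0.74) and Il21 (-0.78). That call was lost in experiment 1 alone (median -0.02, adjusted p = 0.201) and in the exact permutation (adjusted p = 0.0544). Ifng (-0.24, adjusted p = 0.048) passed only with all 17 mice or without anti-RGMb mouse 1, anti-RGMb mouse 3-2, isotype mouse 1 or saline mouse 2-2; of the 13 other fits that left out 1 mouse, that without isotype mouse 1-2 gave the weakest value (-0.15, adjusted p = 0.159). Natural killer cell markers were not called (median -0.03, adjusted p = 0.211, 0 higher, 2 lower and 17 not past, 0 and 1 within the list), but they were called without anti-RGMb mouse 1 (median -0.15, adjusted p = 0.0299) or isotype mouse 1 (-0.10, adjusted p = 0.0335).

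Interstitial macrophage and monocyte markers fell (median -0.60, adjusted p = 1.1e-09, 0.0704 with estimated correlation, 2 higher, 17 lower and 8 not past, 2 and 17 within the list). They included Trem2 (-1.18). Dendritic cell markers were lower (median -0.25, adjusted p = 7.7e-07, 0.112 with estimated correlation, 1 higher, 12 lower and 18 not past, 3 and 16 within the list), as for Itgax (-1.04) and Ccl22. Alveolar macrophage markers were lower (median -0.19, adjusted p = 0.00032, 0.223 with estimated correlation, 2 higher, 10 lower and 12 not past, 4 and 10 within the list). Neutrophil markers were lower (median -0.08, adjusted p = 0.0389, 0.419 with estimated correlation). Of 26 genes, 0 were higher, 6 lower and 20 not past (0 and 6 within the list). They included Acod1 (-1.62). This call was lost without anti-RGMb mouse 1 or 3-2 or isotype mouse 2, 3 or 2-2. These fits gave medians of -0.12 to -0.02 and adjusted p of 0.0623 to 0.196. The exact permutation gave adjusted p = 0.206. Mast cell and basophil markers were not called (median -0.18, adjusted p = 0.14, 3 higher, 5 lower and 12 not past, 4 and 7 within the list), and the exact permutation gave adjusted p = 0.0296. Within this list Mcpt1 and Mcpt2 fell while Gata2 (0.54) and Kit (0.32) rose.

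Goblet cell and mucus genes were lower as a list (median -0.06, adjusted p = 0.0249, 0.453 with estimated correlation). Of 34 genes, 2 were higher, 9 lower and 23 not past (2 and 10 within the list). Slc26a4 (-1.63 ± 0.27), Slc5a1 (-1.09) and Galnt6 (-0.76) fell and Gabrp rose (0.47). The call was lost without isotype mouse 2 or 2-2 or anti-RGMb mouse 1, 2 or 2-2. These fits gave medians of -0.04 to 0.05 and adjusted p of 0.0599 to 0.14. The exact permutation gave adjusted p = 0.685.

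Proliferation genes fell (median -0.97, adjusted p = 4.4e-32, 0.0819 with estimated correlation, 0 higher, 35 lower and 0 not past, 0 and 35 within the list). Endoplasmic reticulum folding and secretion genes fell (median -0.17, adjusted p = 2.1e-10, 0.124 with estimated correlation, 1 higher, 18 lower and 15 not past, 1 and 23 within the list). Complement and pattern recognition genes were lower (median -0.13, adjusted p = 7.2e-05, 0.166 with estimated correlation, 1 higher, 15 lower and 20 not past, 1 and 16 within the list). Eicosanoid pathway genes were lower (median -0.16, adjusted p = 0.00127, 0.102 with estimated correlation, 5 higher, 14 lower and 14 not past, 5 and 16 within the list). Fibroblast and extracellular matrix genes were lower (median -0.11, adjusted p = 0.00475, 0.338 with estimated correlation). Of 34 genes, 5 were higher, 11 lower and 18 not past (6 and 15 within the list). Those lower included Timp1 (-1.67) and Mmp12 (-1.44). The list's call was lost in experiment 2 alone (median -0.15, adjusted p = 0.058).

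Type I interferon stimulated genes were not called (median -0.10, adjusted p = 0.211). Of 30 genes, 0 were higher, 0 lower and 30 not past in limma (0 and 0 at unadjusted p under 0.05, 0 and 0 within the list). Their median was 0.23 in experiment 1 and -0.45 in experiment 2. The list was lower without anti-RGMb mouse 1 (median -0.31, adjusted p = 1.9e-10) or without isotype mouse 1 (-0.20, adjusted p = 0.0255). Without anti-RGMb mouse 1 the antiviral genes Zbp1 (-0.89, adjusted p = 0.00034), Mx1 (-0.78, adjusted p = 0.001) and Oasl1 (-0.59, adjusted p = 0.00699) passed.

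**Figure D2:**
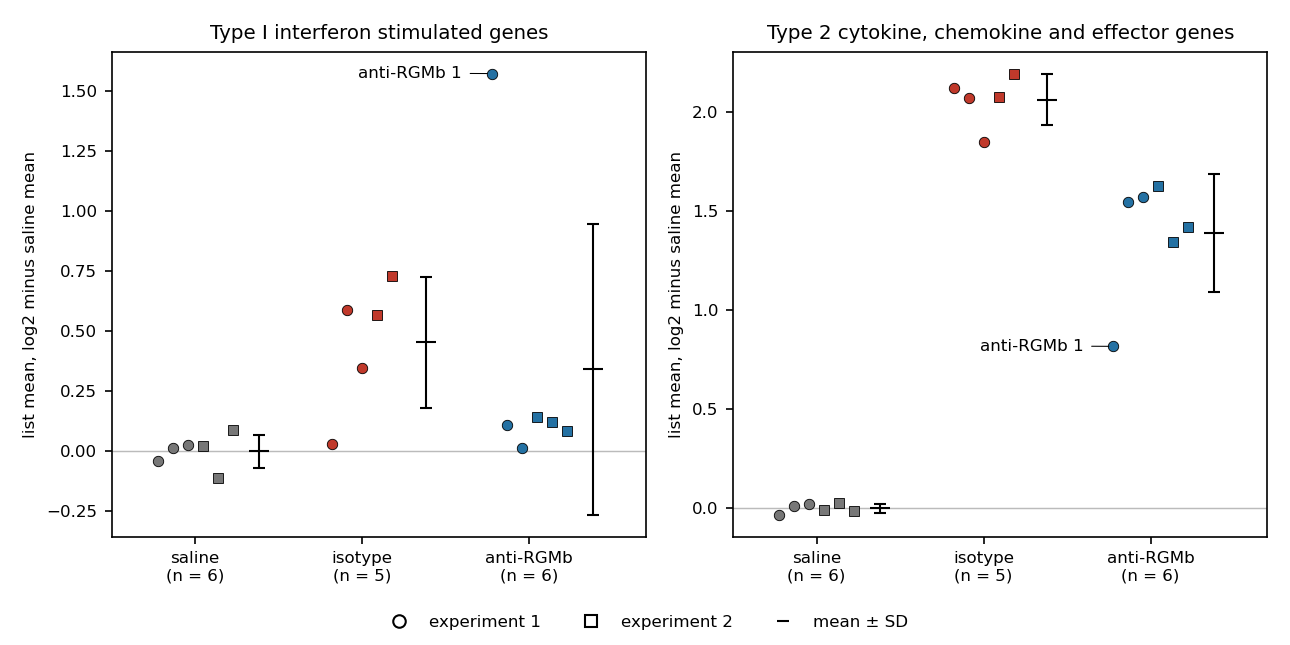
Mean over the 30 measured interferon genes and over the 31 measured type 2 genes in each mouse, minus the saline mean of its experiment (vertical axes, log2 units), in saline (n = 6), isotype (n = 5) and anti-RGMb mice (n = 6), with circles for experiment 1, squares for experiment 2 and bars for the mean ± SD. Anti-RGMb mouse 1 lies at 1.57 for interferon and 0.82 for type 2 genes.

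Lists of resident lung cells were higher with the antibody. Club cell markers rose (median 0.43, adjusted p = 2.1e-11, 0.0704 with estimated correlation). Of 27 genes, 17 were higher, 0 lower and 10 not past (19 and 0 within the list). They included Scgb3a2 (1.07 ± 0.10) and Gsta3 (0.93). Ciliated cell markers were higher (median 0.32, adjusted p = 6.4e-11, 0.137 with estimated correlation, 25 higher, 0 lower and 7 not past, 27 and 0 within the list). Endothelial markers were higher (median 0.33, adjusted p = 3.8e-11, 0.112 with estimated correlation, 21 higher, 0 lower and 10 not past, 23 and 0 within the list). Alveolar epithelial markers were higher (median 0.16, adjusted p = 0.00025, 0.319 with estimated correlation). Of 30 genes, 14 were higher, 2 lower and 14 not past (15 and 3 within the list). Sec14l3 (0.43) and Akap5 (0.66) rose and Fabp5 (-0.74) fell. Smooth muscle and pericyte markers were higher (median 0.18, adjusted p = 0.00125, 0.319 with estimated correlation). Of 26 genes, 8 were higher, 0 lower and 18 not past (9 and 0 within the list). Itga8 (0.78) and Pdgfrb (0.42) rose. The list's call was lost in experiment 1 alone (median 0.09, adjusted p = 0.223). Heart and skeletal muscle markers were higher (median 0.56, adjusted p = 4.9e-06, 0.338 with estimated correlation, 9 higher, 0 lower and 23 not past, 19 and 0 within the list).

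Hub genes were higher with the antibody than with the isotype. Components of the RGM, neogenin and BMP hub rose (median 0.25, adjusted p = 3.1e-08, 0.0704 with estimated correlation). Of 30 genes, 17 were higher, 1 lower and 12 not past (19 and 1 within the list). Rgmb rose by 0.31 ± 0.05 (adjusted p = 0.00053) and Neo1 by 0.47 ± 0.06 (adjusted p = 2.1e-05), and Bmp6 (0.74), Bmp4 (0.34) and Bmpr1a (0.34) were higher. Rgma was higher (0.24, adjusted p = 0.0142), but not past the threshold without isotype mouse 2-2 (0.18, adjusted p = 0.0541). Bmp2 was at 0.17 (adjusted p = 0.249) and Bmpr2 at 0.25 (adjusted p = 0.0512). Bmpr2 passed without saline mouse 2, anti-RGMb mouse 1 or isotype mouse 3 or 2-2 (adjusted p = 0.0207 to 0.0486). BMP target genes and antagonists rose (median 0.29, adjusted p = 2.3e-07, 0.134 with estimated correlation). Of 31 genes, 17 were higher, 1 lower and 13 not past (18 and 1 within the list). They included Smad6 (0.55), Smad7 (0.28), Id1 (0.29), Id3 (0.41) and Tmem100 (0.67).

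Adipose markers were higher (median 0.18, adjusted p = 0.0226, 0.364 with estimated correlation). Of 20 genes, 5 were higher, 1 lower and 14 not past (6 and 1 within the list). Plin4 (0.43) rose. The list's call was lost without anti-RGMb mouse 3 (median 0.13, adjusted p = 0.11) or isotype mouse 2-2 (0.15, adjusted p = 0.0503). Erythroid markers were not called (median 0.19, adjusted p = 0.0853, 6 higher, 1 lower and 6 not past, 7 and 1 within the list), but they were called without anti-RGMb mouse 1 (median 0.20, adjusted p = 0.0413). Immediate early and stress genes were not called (median 0.12, adjusted p = 0.136, 10 higher, 3 lower and 20 not past, 13 and 4 within the list), but they were called without anti-RGMb mouse 3-2 (median 0.16, adjusted p = 0.0132). Circadian clock genes (median 0.09, adjusted p = 0.756, 6 higher, 4 lower and 8 not past, 7 and 4 within the list) and thymus and immature lymphocyte markers (median 0.02, adjusted p = 0.989, 2 higher, 3 lower and 18 not past, 2 and 3 within the list) were not called, and the mean of the last was -0.01. With a preset correlation 27 lists were called (9 higher and 18 lower), and camera with an estimated correlation called 0, with 12 at unadjusted p under 0.05. The exact permutation of list means called 24. Some called medians moved by over 1.5 times without 1 mouse: alveolar macrophage (-0.13 without anti-RGMb mouse 2), complement (-0.08 without anti-RGMb mouse 3-2), type 1 and type 17 (-0.09 without anti-RGMb mouse 2-2, -0.08 without isotype mouse 1-2), goblet (-0.13 without anti-RGMb mouse 3, -0.12 without isotype mouse 3) and neutrophil genes (-0.13 and -0.14 without isotype mouse 1 or 1-2). Without a term for the experiment limma called 0 genes (73 at unadjusted p under 0.05).

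Anti-RGMb and saline mice were compared to ask what remained of the allergen's changes under the antibody (6 mice each). Some genes of eosinophils, macrophages and mucus stayed far above saline. Rnase2a was higher by 6.78 ± 0.39 log2 units, Clca1 by 6.09 ± 0.61, Ccl8 by 4.83 ± 0.18 and Cd5l by 4.16 ± 0.55, and Pdcd1lg2 by 1.36 ± 0.14 (adjusted p = 5.0e-06). Il13 (0.18, adjusted p = 0.462), Il33 (0.20, adjusted p = 0.277) and Il5 (0.04, adjusted p = 0.903) were not past the threshold. In all, 1284 genes passed, 842 higher and 442 lower, of which 122 and 1 changed at least 2-fold. All 1284 had the same sign in both experiments, with 644 higher and 119 lower called in experiment 1 and 524 and 129 in experiment 2.

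Other large rises were Retnla (4.13), Saa3 (3.58), Serpinb2 (3.54), a plasminogen activator inhibitor of macrophages, Chil3 (3.49), Arg1 (3.22), Slc26a4 (3.21), Prg4 (3.08), lubricin, and Chil4 (2.93). Among the 12 largest falls, those called whichever mouse was left out were Pon1 (-1.01 ± 0.22), Col12a1 (-0.81), Scel (-0.75), Ccn1 (-0.71), Ecm2 (-0.57), Grp (-0.56), Igfbp3 (-0.56) and Myct1 (-0.53). Anti-RGMb mouse 1 was the lowest of its group for Arg1 (0.10 above saline, against 3.06 to 4.23), Cd5l (0.85, against 4.23 to 5.12), Prg4 (0.17, against 2.93 to 4.07), Serpinb2 (0.61, against 3.54 to 4.43) and Chil3 (2.25, against 3.43 to 4.01).

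Type 2 genes stayed higher than in saline mice (median 0.47, adjusted p = 1.2e-24). Of 31 genes, 14 were higher, 0 lower and 17 not past (18 and 0 within the list). Ccl11 was 3.03-fold and Ccl24 2.14-fold higher. Il4 was at 0.47 (adjusted p = 0.0885), past the threshold without isotype mouse 3 (adjusted p = 0.0484) or isotype mouse 2-2 (adjusted p = 0.0223), and Il17rb at 0.27 (adjusted p = 0.0928), past it without isotype mouse 2-2 (adjusted p = 0.00961). Eosinophil markers were higher (median 0.75, adjusted p = 2.8e-24, 12 higher, 0 lower and 4 not past, 14 and 0 within the list). They included Ccr3 (2.05), the eotaxin receptor, and Alox15 (2.30). Goblet cell and mucus genes were higher (median 0.22, adjusted p = 2.2e-10, 0.068 with estimated correlation, 9 higher, 0 lower and 25 not past, 13 and 0 within the list). Muc5ac was higher by 2.06 ± 0.60 (adjusted p = 0.0488), but not in 10 fits, without any 1 of the 6 saline mice or without anti-RGMb mouse 2, 3, 1-2 or 3-2 (weakest without anti-RGMb mouse 3, 1.79, adjusted p = 0.121). Mast cell and basophil markers were higher (median 0.21, adjusted p = 2.0e-07, 5 higher, 0 lower and 15 not past, 11 and 0 within the list). Cpa3 was higher (1.16), but the list was not called with the dimmest 40% of genes left out (median 0.00, adjusted p = 0.221).

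Interstitial macrophage and monocyte markers stayed higher (median 0.73, adjusted p = 6.7e-26, 17 higher, 0 lower and 10 not past, 19 and 0 within the list). Dendritic cell markers were higher (median 0.31, adjusted p = 2.8e-24, 15 higher, 0 lower and 16 not past, 18 and 0 within the list). They included the chemokine gene Ccl17 (1.48). Alveolar macrophage markers were higher (median 0.23, adjusted p = 1.4e-08, 0.0621 with estimated correlation, 9 higher, 1 lower and 14 not past, 12 and 2 within the list). Neutrophil markers were higher (median 0.24, adjusted p = 3.8e-07, 0.068 with estimated correlation, 5 higher, 0 lower and 21 not past, 5 and 0 within the list). Complement and pattern recognition genes were higher (median 0.37, adjusted p = 1.2e-22, 19 higher, 0 lower and 17 not past, 22 and 0 within the list). Proliferation genes stayed higher (median 0.85, adjusted p = 3.4e-47, 31 higher, 0 lower and 4 not past, 34 and 0 within the list). Eicosanoid pathway genes were higher (median 0.06, adjusted p = 7.1e-08, 9 higher, 0 lower and 24 not past, 14 and 2 within the list).

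Lymphocyte lists stayed higher. Markers of T helper 2 and innate lymphoid group 2 cells were higher (median 0.27, adjusted p = 2.2e-10, 8 higher, 0 lower and 16 not past, 13 and 0 within the list). Regulatory T cell markers were higher (median 0.31, adjusted p = 6.0e-10, 9 higher, 0 lower and 11 not past, 12 and 1 within the list). Foxp3 was higher by 0.38 ± 0.07 and Il10 was at -0.06 (adjusted p = 0.911). T cell markers were higher (median 0.11, adjusted p = 0.00046, 0.485 with estimated correlation, 4 higher, 0 lower and 24 not past, 6 and 1 within the list). Type 1 and type 17 T cell genes were higher (median 0.09, adjusted p = 4.9e-05, 0.218 with estimated correlation, 3 higher, 0 lower and 18 not past, 5 and 0 within the list), with Ifng at -0.03 (adjusted p = 0.9). Plasma cell and immunoglobulin genes were higher (median 0.18, adjusted p = 1.5e-05, 0.239 with estimated correlation, 2 higher, 0 lower and 17 not past, 6 and 2 within the list), Jchain (2.63) among them. B cell markers were higher (median 0.06, adjusted p = 0.00999, 0.525 with estimated correlation, 4 higher, 0 lower and 25 not past, 5 and 0 within the list). The call was lost without anti-RGMb mouse 2 (median 0.03, adjusted p = 0.054) or saline mouse 2-2 (0.04, adjusted p = 0.0704). Natural killer cell markers were not called (median 0.00, adjusted p = 0.366, 1 higher, 0 lower and 18 not past, 1 and 0 within the list).

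Type I interferon stimulated genes were higher as a list (median 0.30, adjusted p = 5.1e-06, 0.485 with estimated correlation, 1 higher, 0 lower and 29 not past, 0 and 0 within the list). At unadjusted p under 0.05 limma gave 9 higher and 0 lower members. Without anti-RGMb mouse 1 the list was not called (median 0.07, adjusted p = 0.0623). Fibroblast and extracellular matrix genes were higher (median 0.11, adjusted p = 8.3e-05, 0.229 with estimated correlation, 7 higher, 1 lower and 26 not past, 10 and 3 within the list). Endoplasmic reticulum folding and secretion genes were higher (median 0.04, adjusted p = 0.00635, 0.485 with estimated correlation, 2 higher, 0 lower and 32 not past, 2 and 0 within the list), a call that ended without saline mouse 1 (median 0.03, adjusted p = 0.0924). Immediate early and stress genes were higher (median 0.11, adjusted p = 0.0135, 0.485 with estimated correlation, 5 higher, 2 lower and 26 not past, 9 and 5 within the list), a call that ended without saline mouse 2 (median 0.08, adjusted p = 0.0691), anti-RGMb mouse 2 (0.08, adjusted p = 0.0595) or anti-RGMb mouse 2-2 (0.08, adjusted p = 0.0749), and their median was -0.01 in experiment 2 alone.

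Resident lists and the hub lay close to saline. Components of the hub were lower (median -0.13, adjusted p = 0.00017, 0.11 with estimated correlation). Of 30 genes, 1 was higher, 5 lower and 24 not past (1 and 10 within the list). Rgmb (-0.13, adjusted p = 0.173), Neo1 (-0.05, adjusted p = 0.67), Bmpr1a (-0.14, adjusted p = 0.31) and Bmpr2 (-0.18, adjusted p = 0.242) were not past the threshold, and Ntn4 (-0.38) was lower. Bmp4 was at -0.25 (adjusted p = 0.0676) and passed without isotype mouse 3 (adjusted p = 0.0389), isotype mouse 1-2 (adjusted p = 0.0492) or isotype mouse 2-2 (adjusted p = 0.0296). Rgma was lower (-0.23, adjusted p = 0.033) except in 8 fits, without saline mouse 1, 3, 1-2 or 2-2 or anti-RGMb mouse 2, 3, 1-2 or 2-2 (weakest without saline mouse 1-2, -0.21, adjusted p = 0.0878). Bmp2 was lower (-0.32, adjusted p = 0.0443) except in 11 fits, without saline mouse 1, 2, 1-2 or 3-2, isotype mouse 1 or 2, or anti-RGMb mouse 1, 2, 3, 1-2 or 3-2 (weakest without saline mouse 1-2, -0.26, adjusted p = 0.118). BMP target genes and antagonists were lower (median -0.14, adjusted p = 0.00064, 0.344 with estimated correlation). Of 31 genes, 1 was higher, 5 lower and 25 not past (1 and 9 within the list). Id3 (-0.34) was lower and Fst (0.54) higher, and Id1 (-0.03), Smad6 (-0.23) and Smad7 (-0.15) were not past the threshold.

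Endothelial markers were lower than in saline mice (median -0.11, adjusted p = 0.0004, 0.404 with estimated correlation, 1 higher, 6 lower and 24 not past, 2 and 10 within the list). Ciliated cell markers were lower (median -0.11, adjusted p = 0.00169, 0.485 with estimated correlation, 0 higher, 1 lower and 31 not past, 0 and 1 within the list). The call was lost in experiment 1 alone (adjusted p = 0.282). Alveolar epithelial markers were lower (median -0.10, adjusted p = 0.00914, 0.485 with estimated correlation, 2 higher, 3 lower and 25 not past, 2 and 10 within the list), a call that ended without anti-RGMb mouse 2 (median -0.08, adjusted p = 0.0507). Smooth muscle and pericyte markers were lower (median -0.08, adjusted p = 0.036, 0.525 with estimated correlation, 0 higher, 0 lower and 26 not past in limma, 1 and 5 at unadjusted p under 0.05, 0 and 0 within the list), a call that ended without anti-RGMb mouse 1 (median -0.05, adjusted p = 0.484), saline mouse 3 (-0.06, adjusted p = 0.0766), saline mouse 3-2 (-0.07, adjusted p = 0.127) or anti-RGMb mouse 3-2 (-0.10, adjusted p = 0.0614). Club cell markers were not called (median -0.07, adjusted p = 0.153, 1 higher, 5 lower and 21 not past, 1 and 7 within the list), and their mean was 0.18, with Retnla at 4.13.

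Heart and skeletal muscle markers were not called (median -0.19, adjusted p = 0.0902, 0 higher, 0 lower and 32 not past in limma, 0 and 1 at unadjusted p under 0.05, 0 and 0 within the list), but they were called without saline mouse 2 (median -0.30, adjusted p = 0.00484), saline mouse 3 (-0.27, adjusted p = 0.00688), saline mouse 1-2 (-0.26, adjusted p = 0.019) or anti-RGMb mouse 3 (-0.30, adjusted p = 0.00195). Adipose markers were not called (median 0.06, adjusted p = 0.124, 0 higher, 0 lower and 20 not past in limma, 2 and 0 at unadjusted p under 0.05, 0 and 0 within the list), but they were called without saline mouse 2-2 (median 0.10, adjusted p = 0.0151) or anti-RGMb mouse 2 (0.12, adjusted p = 0.0331). Erythroid markers (median 0.00, adjusted p = 0.654, 0 higher, 0 lower and 13 not past in limma, 0 and 0 at unadjusted p under 0.05, 0 and 0 within the list), with a mean of 0.02, circadian clock genes (median -0.05, adjusted p = 0.765, 2 higher, 2 lower and 14 not past, 4 and 4 within the list), with a mean of 0.01, and thymus and immature lymphocyte markers (median 0.02, adjusted p = 0.688, 1 higher, 0 lower and 22 not past, 1 and 1 within the list) were not called. Camera called 27 lists (21 higher and 6 lower) with a preset correlation. With an estimated correlation 10 held (adjusted p = 0.0015 to 0.0405): type 2, eosinophil, mast cell, T helper 2, regulatory T, interstitial macrophage, dendritic cell, proliferation, eicosanoid and complement genes. Called medians that moved by over 1.5 times without 1 mouse were those of B cell (0.10 without anti-RGMb mouse 3-2 or saline mouse 1, 0.03 without saline mouse 3-2), T cell (0.04 without anti-RGMb mouse 1, 0.07 without saline mouse 2-2), neutrophil (0.39 without anti-RGMb mouse 1), fibroblast (0.05 without anti-RGMb mouse 3), eicosanoid (0.12 without anti-RGMb mouse 3-2), alveolar epithelial (-0.06 without saline mouse 3) and immediate early genes (0.07 without saline mouse 3). The exact permutation called 21, all but T cell (adjusted p = 0.0541), B cell (0.111), ciliated (0.109), smooth muscle (0.0887), endoplasmic reticulum (0.106) and immediate early genes (0.425). Without a term for the experiment limma called 10 genes (101 at unadjusted p under 0.05).

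**Figure D3:**
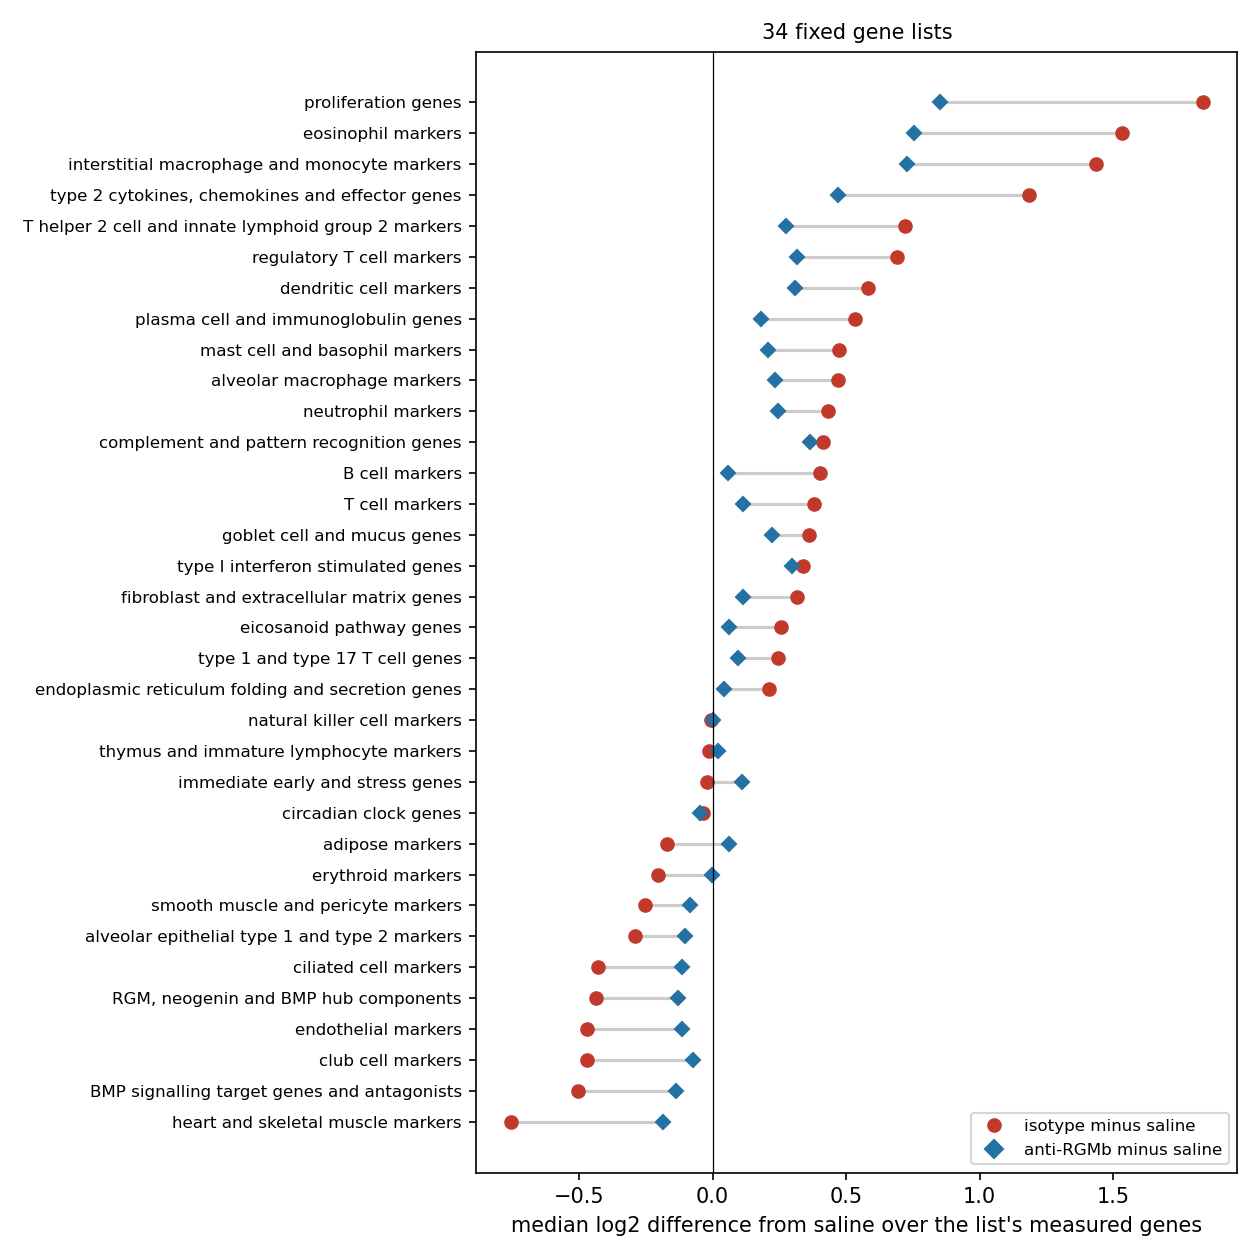
Median log2 difference from saline over the measured genes of each of 34 lists (horizontal axis, log2 units) in isotype (red circles, n = 5) and anti-RGMb mice (blue diamonds, n = 6), with a grey line between the 2. Proliferation genes have the highest isotype median of the 34 lists (1.84, against 0.85 with the antibody), and heart and skeletal muscle markers the lowest (-0.75, against -0.19).

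The size of the allergen's change in each mouse was read from the allergen score. Isotype mice scored 2.53 ± 0.30 (SD, n = 5), anti-RGMb mice 1.19 ± 0.11 (SD, n = 6) and saline mice 0.00 ± 0.11 (SD, n = 6). Each anti-RGMb mouse (1.05 to 1.29) lay below each isotype mouse (2.00 to 2.72) and above each saline mouse (-0.17 to 0.10). The mean of both experiments' differences between anti-RGMb and isotype mice was -1.37 (exact permutation p = 0.005, the smallest that 200 relabellings can give). It was -1.19 in experiment 1 and -1.55 in experiment 2, each with an exact permutation p of 0.1, the smallest that 20 and 10 relabellings can give. Isotype mice differed from saline mice by 2.56 (exact permutation p = 0.005, the smallest of 200), and anti-RGMb mice from saline mice by 1.19 (exact permutation p = 0.005, the smallest of 400). Under the antibody 46.5% of the score was kept, 51.4% in experiment 1 and 42.1% in experiment 2.

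**Figure D4:**
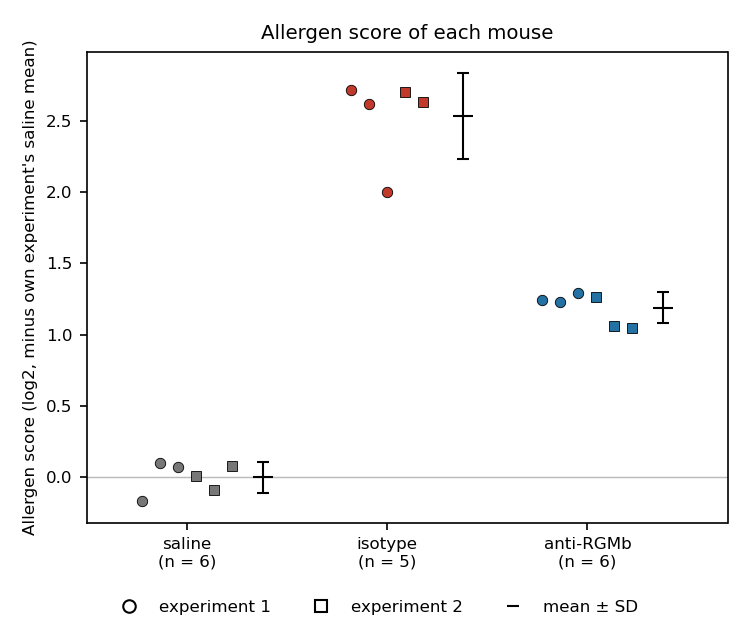
Allergen score of each mouse (vertical axis, log2 units above the saline mean of its experiment) in saline (n = 6), isotype (n = 5) and anti-RGMb mice (n = 6), with circles for experiment 1, squares for experiment 2 and bars for the mean ± SD. Anti-RGMb mice lie at 1.05 to 1.29.

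Gene by gene, the antibody's changes opposed the allergen's. Of the 2878 genes raised in isotype mice, 1897 fell with the antibody, against 289 expected from the counts alone, and of the 4156 lowered, 2130 rose, against 463 expected. Because both comparisons share the isotype arrays, the overlap was also taken between experiments. In fits to the arrays of 1 experiment alone, which call other numbers of genes than the model of both, 1847 genes were raised by the allergen in experiment 1. Of these, 1201 were among the 1661 lowered by the antibody in experiment 2 (155 expected), and of 2448 lowered ones 996 were among the 1290 raised (160 expected). The other way round, 461 of 2278 raised genes were lowered (59.6 expected) and 401 of 2442 lowered genes were raised (62.2 expected). Genes that limma called with the same sign in both comparisons numbered 0 higher and 0 lower with all arrays (5 and 1 at unadjusted p under 0.05). Without shared arrays they were 7 and 0 (121 and 206 expected), and 0 and 0 the other way round (58.0 and 63.9 expected).

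Across genes, which are not independent replicates, changes by the allergen and by the antibody had a Pearson's r of -0.90 over both experiments. Shared arrays without any effect gave -0.55 in simulation, and the covariance was -0.094 against -0.0047 simulated. With no shared arrays r was -0.74 (Spearman's rho -0.68) for the allergen in experiment 1 and the antibody in experiment 2, and -0.77 (Spearman's rho -0.64) the other way round, against simulated values of 0.0026 and 0.0035. Without isotype mouse 1-2 the first of these was -0.64. Changes of 1 comparison were related between experiments with r of 0.90 for the allergen and 0.70 for the antibody, which makes 5 relations computed.

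**Figure D5:**
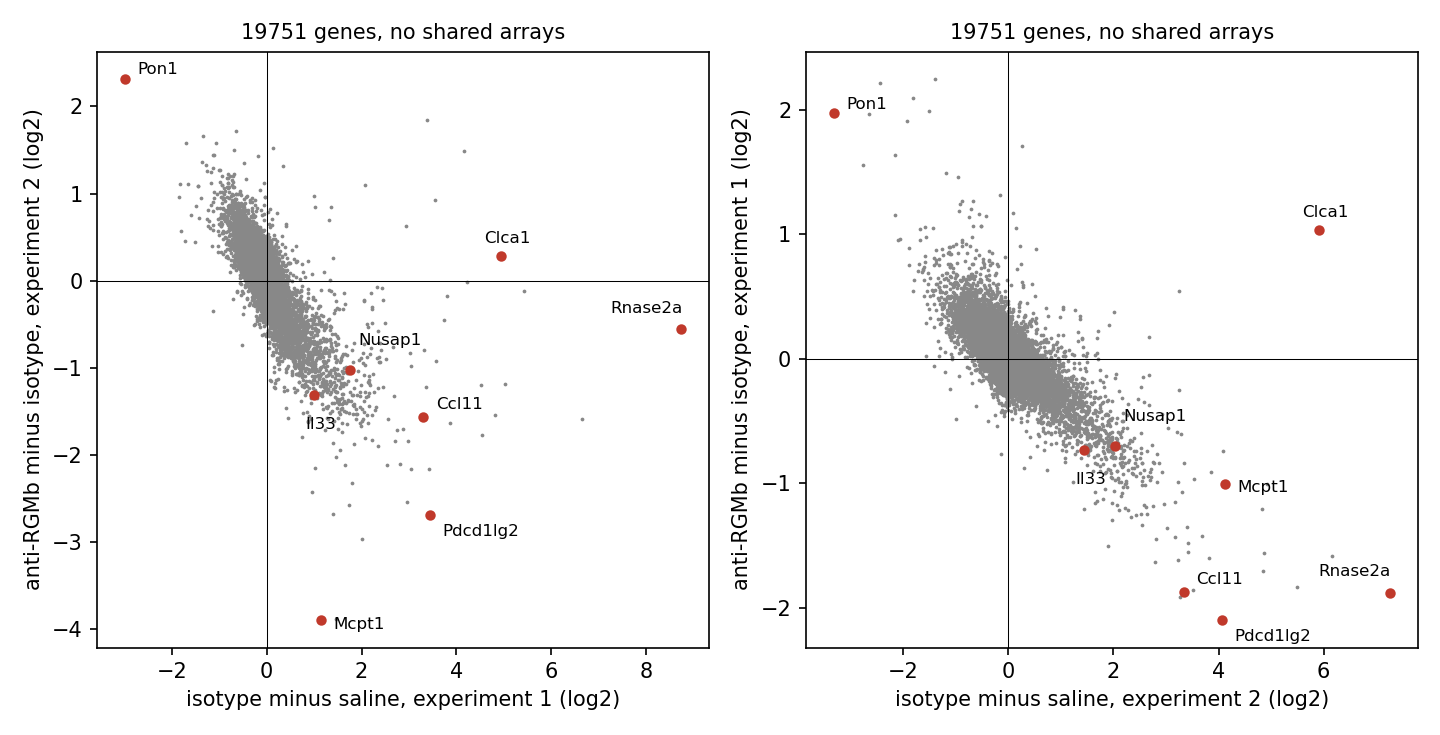
Log2 difference between isotype and saline mice in 1 experiment (horizontal axes) against that between anti-RGMb and isotype mice in the other (vertical axes, log2 units), with 1 point per gene (19751 genes) and 8 genes in red. Across genes r is -0.74 on the left and -0.77 on the right; Clca1 lies above 0 on both axes in both panels.

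Part of the allergen's change remained. Of the 2878 raised genes, 818 were also called higher in anti-RGMb than in saline mice, and of the 4156 lowered, 434 were also lower. Both comparisons share the saline arrays. In fits to 1 experiment's arrays, 420 of the genes raised by the allergen in experiment 1 were higher in anti-RGMb than in saline mice in experiment 2 (41.2 expected) and 32 of the lowered ones lower (4.96 expected), and the other way round 443 (54.1 expected) and 59. The median raised gene kept 36.1% of its change, the median lowered gene 37.4%, and the median of the 531 genes raised at least 2-fold 47.9%. A total of 152 raised genes were called above saline under the antibody without a call for a fall. Genes called between anti-RGMb and saline mice but not between isotype and saline mice numbered 32 (24 higher and 8 lower), and 12 of them were also called between anti-RGMb and isotype mice.

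The experiments differed in the size of some changes. The interaction passed for 132 genes between isotype and saline mice, 125 of them larger in experiment 2 in the same direction and 7 of opposite sign, and for 93 genes between anti-RGMb and isotype mice, 83 of them larger in experiment 2 and 10 of opposite sign. The mast cell protease genes Mcpt1 and Mcpt2 were among them, with a rise by the allergen of 1.15 and 1.46 in experiment 1 and of 4.13 and 4.93 in experiment 2. These counts depended on single mice. Without isotype mouse 1-2 they were 445 and 811, but this fit, like that without 2-2, has 1 isotype mouse in experiment 2 and takes its spread from other groups. The first count was 74 without saline mouse 3, 76 without saline mouse 1-2, 81 without saline mouse 2 or 3-2, and 83 without isotype mouse 3. The second was 61, 43, 53 and 45 without saline mouse 3, 1-2, 2-2 or 3-2, 24, 36, 40, 33, 25 and 50 without anti-RGMb mouse 1, 2, 3, 1-2, 2-2 or 3-2, and 26 and 39 without isotype mouse 3 or 2-2.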

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

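Of the tests below, those of heart and skeletal muscle genes and of a wrong label and array noise for anti-RGMb mouse 1 were chosen only after the result was seen.

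Lists of resident lung cells were lower in isotype than in saline mice, calls that were lost with an estimated correlation (adjusted p = 0.132 to 0.304), and RNA of infiltrating cells may dilute resident RNA by 1 factor. If it did, the 5 lists' medians would be alike. They were -0.47 (endothelial), -0.43 (ciliated), -0.42 (club), -0.29 (alveolar) and -0.25 (smooth muscle), a gap of 0.22. Shuffling 144 genes among the lists gave this or more with a permutation p of 0.341 (100000 permutations). As this keeps the spread between genes, it cannot show 1 factor. Hub genes had a median of -0.43 against -0.38 for 143 resident genes. The difference was -0.057 (95% bootstrap interval over genes -0.15 to 0.15), so no further fall was shown. For heart and skeletal muscle genes, whose median in each mouse changed by -0.32 ± 0.20 (SE over mice, exact permutation p = 0.195) relative to the resident genes, dilution cannot be told apart with so few mice, and dilution alone cannot raise fibroblast and matrix genes (median 0.32) or alveolar macrophage genes (0.47). Nor can it raise the 3 endothelial and 3 alveolar markers that rose. For the medians of the 5 lists and the hub it stays open, as does a lower expression per cell, which was not tested.

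Anti-RGMb mouse 1 had the highest interferon genes of its group, with a list mean of 1.57 against 0.01 to 0.14 (a gap of 0.918 of the group's range), and the lowest type 2 genes, with 0.82 against 1.34 to 1.63 (gap 0.651). A saline mouse under a wrong label is argued against by its allergen score of 1.24, among the other anti-RGMb mice (1.05 to 1.29) and above the saline mice (-0.17 to 0.10). Noise of 1 array is argued against by a second list of 21 interferon-induced genes outside all fixed lists, since 100% of them lay above the other 5 mice. This list had a mean of 0.79 in this mouse against -0.08 to 0.05 in the others (gap 0.849), which is consistent with an interferon response of this mouse. The design names no such group, so the source of that response stays open.

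In these mice, goblet cell and mucus genes raised by the allergen kept a larger median share of their rise under the antibody than other raised genes did. Saturation of bright probe sets is argued against, since the median level of the 19 raised goblet genes differed by -3.71 log2 units from the level that bounds the brightest 0.1% of values in experiment 2 and by -5.21 in experiment 1. Scaling with the size of the allergen's change stays open. These genes kept a median of 66.4%, and 10000 lists with rises of like size 32.7% to 52.4% (central 95%). Without the 3 genes below the arrays' lower quartile in saline mice it was 59.0% against 31.2% to 51.7%. These ranges leave out the spread among mice. Chance among mice stays open too, as the goblet genes' mean change kept 76.9% and the allergen score 46.5% (exact permutation p = 0.23, 200 relabellings). Of the 19, 8 kept at least 75%, among them Muc5b (107%), Bpifb1 (96.1%) and Muc5ac (90.8%), and a weaker action of the antibody on goblet cells may be a cause but is not shown.

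Among 327 groups of mice checked for a single value far from the rest, 22 stood out, and chance gives about 1 in 20, or 16.4. The values below are the gap of that mouse to the nearest other, as a share of the group's range. In anti-RGMb mouse 1 the gap was 0.718 for Arg1, 0.790 for Cd5l, 0.671 for Chil3, 0.843 for Il13 (-0.29 against 0.23 to 0.33), 0.707 for Prg4 and 0.765 for Serpinb2, all low. The same mouse was high for Foxp3 (gap 0.639), type 1 and type 17 T cell genes (gap 0.652) and dendritic cell markers (gap 0.626). Anti-RGMb mouse 3-2 was low for Bmp2 (gap 0.945, -0.63 against -0.26 to -0.24) and Myct1 (gap 0.654) and high for Il17a (gap 0.715). Anti-RGMb mouse 3 was low for Il17rb (gap 0.822) and high for fibroblast and matrix genes (gap 0.813). Anti-RGMb mouse 2-2 was high for Scel (gap 0.6252). Isotype mouse 2 was high for Myl7 (gap 0.764, -0.57 against -2.94 to -2.38) and for the heart and skeletal muscle list (gap 0.915, -0.31 against -0.95 to -0.89). Isotype mouse 1 was high for plasma cell and immunoglobulin genes (gap 0.730, 1.59 against 0.56 to 0.84). Isotype mouse 3 was low for the allergen score (gap 0.858, 2.00 against 2.61 to 2.72). Saline mouse 2-2 was low for Il10 (gap 0.656).

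For 5 named genes the interaction between group and experiment passed the threshold. The values are log2 changes in experiment 2 minus those in experiment 1, first for isotype against saline and then for anti-RGMb against isotype. They were 2.98 (adjusted p = 0.00057) and -2.90 (adjusted p = 0.00214) for Mcpt1, and 3.47 (adjusted p = 0.00206) and -2.88 (adjusted p = 0.0165) for Mcpt2. Tm4sf19 had 1.67 (adjusted p = 0.00937) and -1.54 (adjusted p = 0.0262), Il10 had 1.03 (adjusted p = 0.00961) and -0.96 (adjusted p = 0.0262), and Dpep1 had -1.15 (adjusted p = 0.00975) and 1.08 (adjusted p = 0.0263).

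Among the 3325 probe sets without 1 gene symbol, which no comparison used, 781 passed the threshold between isotype and saline mice (470 higher), 374 between anti-RGMb and isotype mice (144 higher) and 128 between anti-RGMb and saline mice (106 higher).

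Other splits of the same arrays were fitted, 100 per comparison with the real one. Chance can be excluded for the number of genes, which only the real split reached. The numbers were 7034, 4180 and 1284 in the 3 comparisons in turn (highest others 4575, 2435 and 5). Of 100 splits, 9, 4 and 4 reached 28, 27 and 27 lists (highest others 30, 28 and 27). Chance cannot be excluded for the 28 lists and is argued against for each 27.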

How the results depend on the processing

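The alternatives without 3 arrays of experiment 2, with the lower quartile as a covariate and with experiment 2 rescaled, and their tests, were chosen only after the results were seen. Over all alternatives, 93.5% of 16357 values for 498 gene results and 94.7% of 2856 values for 102 list results kept their direction and their side of the threshold. For genes 948 became weaker, 118 stronger and 0 reversed, and for lists 121, 29 and 1, the reversed one being immediate early genes in anti-RGMb against saline mice in experiment 2 alone (median -0.0082, adjusted p = 0.877), with fewer mice. Gene counts are given below as isotype against saline, anti-RGMb against isotype, and anti-RGMb against saline. Without a term for the experiment they were 35, 0 and 10, because the arrays' levels differ between experiments. Fits to the arrays of experiment 1 alone gave 4295, 1020 and 550, and of experiment 2 alone 481 for the third, with fewer mice. A 1.5-fold minimum, which is stricter, gave 1754, 654 and 357. The third count was 1973 at an adjusted p under 0.10, 2009 with only the 2 groups and 2541 with array weights, and the cause was not tested for the last 2. An estimated correlation left 9, 0 and 10 lists, since it widens the error of each list. Counts for the interaction were 23 and 7 with array weights, 32 and 3 with experiment 2 rescaled and 308 and 184 at an adjusted p under 0.10, and the second was 53 with arrays centred on their medians; the cause was not tested. The allergen score differed by -1.19 and -1.55 in experiment 1 or 2 alone, where the exact p cannot fall under 0.1. Spearman's rho was -0.639 for the allergen in experiment 2 and the antibody in experiment 1, and the cause was not tested.

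Leaving out 1 mouse gave 6458 to 7358, 3581 to 4466 and 913 to 1540 genes, 28 to 28, 24 to 29 and 25 to 28 lists, and interaction counts of 74 to 445 and 24 to 811. The score difference was -1.54 to -1.30, and the relations across genes were -0.756 to -0.638 and -0.809 to -0.677. Mouse number as a further term, which rests on an unstated pairing, gave 6623, 3813 and 1128 genes. Without the 3 arrays of experiment 2 with the highest lower quartile the counts were 6833, 3548 and 1155. In experiment 2 isotype mice number 2, and signal near the arrays' background limits what dim genes can show.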

Other observations

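The tests on genes that kept their rise and on genes called only against saline, and the slopes between experiments, were chosen only after the results were seen.

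Of the 531 genes raised at least 2-fold by the allergen, 26 kept at least 80% of their rise, 23 of them past the threshold against saline, and the genes named here were chosen after their values were seen. In saline mice 10 of the 26 lay below the arrays' lower quartile, where a share kept is uncertain. Of the others, Fabp7 (1.96 ± 0.27, 128% kept), Muc5b (1.81 ± 0.52, 107%), Clec4e (1.07 ± 0.17, 105%), Bpifb1 (2.63 ± 0.60, 96.1%), Itgam (2.24 ± 0.22, 88.9%), Chil3 (3.49 ± 0.19, 88.2%), Retnla (4.13 ± 0.27, 87.3%), Mgl2 (1.76 ± 0.12, 86.9%) and Siglec1 (1.01 ± 0.21, 81.9%) were higher than in saline mice. In the same set 2 genes also fell with the antibody, Rnase2a (-1.32) and Adgre1 (-0.41), and 15 of the 26 were lowest in anti-RGMb mouse 1 among its group.

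Of the 24 genes called higher than in saline mice in anti-RGMb but not in isotype mice, some were chosen after their values were seen: Angptl4 (0.76 ± 0.15), a lipoprotein lipase inhibitor, Inhbb (0.50 ± 0.08), an activin subunit gene, Cldn1 (0.37 ± 0.11), a tight junction gene, and Nfkbia (0.26 ± 0.06), an inhibitor of NF-kappa-B. Others were Ifitm6 (0.98 ± 0.22), Cebpd (0.50 ± 0.11) and Tsc22d3 (0.41 ± 0.08). Against isotype mice Ifitm6 (0.83), Inhbb (0.55), Cldn1 (0.49), Cebpd (0.40) and Tsc22d3 (0.37) were also higher, while Angptl4 (0.35, adjusted p = 0.138) and Nfkbia (0.16, adjusted p = 0.11) were not past the threshold.

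Since glucocorticoids induce Tsc22d3 and Cebpd, other genes they induce might be higher in antibody-treated mice. A list of 17 such genes outside all fixed lists was higher in anti-RGMb than in saline mice by 0.19 (exact permutation p = 0.005, the smallest of 400) and than in isotype mice by 0.25 (exact permutation p = 0.005, the smallest of 200). Isotype and saline mice differed by -0.07 (exact permutation p = 0.25). The members past the threshold against saline were 4, Fkbp5 (0.58), Mt1 (0.57), Mt2 (1.10) and Ddit4 (0.46), all also higher in isotype than in saline mice. Against isotype mice 8 members were higher and 1, Fkbp5 (-0.52), lower. These 8 were the ones lower in isotype than in saline mice and 0 of them passed against saline, so the hypothesis stays open.

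Changes between isotype and saline mice were on the whole larger in experiment 2, though some were smaller, such as Retnla (5.43 in experiment 1 and 3.86 in experiment 2), and the interaction passed for 0 genes with a smaller change of the same sign. Across 7034 genes past the threshold the slope of experiment 2 on experiment 1 was 1.31, and it was 1.33 and 1.34 without either isotype mouse of experiment 2. The slope of saline levels across genes was 1.00. These slopes were run as tests of a wider scale and of 1 isotype mouse, a pattern then left unweighed in favour of anti-RGMb mouse 1.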
